A study of Mus musculus with 32 samples.

How the data were processed

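The data are bulk RNA sequencing of 32 libraries of CD8+ Thy1.1+ Pmel T cells from C57BL/6 mice, in 8 groups of 4. Per the labels' protocols, lymph nodes were dissociated mechanically, skin was digested with collagenase IV, lung with Liberase, and liver was meshed and digested with collagenase IV. Lung and liver cells then passed a Percoll gradient. The dissociation of spleen and tumor is not given in the sources used here. Per the submitters' processing notes, reads were aligned with Bowtie to the mm10 build. The program's version, the annotation and the counting step are not given in the sources used here.

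The table used here holds natural log values of TPM + 1 as deposited. This was settled from the values themselves. All cells converted back are multiples of 0.01 TPM, within 0.0001 of that unit, and each library sums to between 999999.06 and 1000000.8 TPM. The authors deposited TPM in this form and not read counts, so depth and counting error per library are unknown. The design, written before the data were examined, had assumed counts or normalized values, and the branch for normalized values was used. Of 46517 gene names, 42052 (90.4%) matched 1 symbol of the reference annotation.

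TPM + 1 was converted to log2. Of 42409 genes above 0 in any library, the 19738 with at least 1 TPM in 4 or more libraries were tested. All 8 groups entered 1 linear model with limma 3.58.1 in R 4.3.3, with a trend of the variance with abundance and 24 residual degrees of freedom. The p-values of each of the 9 comparisons were adjusted by Benjamini-Hochberg, and genes under 0.05 were called. The fit and its alternatives were tested on simulated data with the spreads of these groups and 200 changed genes. False shares there do not carry over to real calls. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 served for quality measures, scores and figures.

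Lists of 15 programs were fixed in the same design: residency, circulation, naive and central memory, cytotoxic effector, inhibitory receptor and exhaustion, proliferation, type I interferon response, immediate early, heat shock, lipid uptake and fatty acid oxidation, glycolysis and hypoxia, oxidative phosphorylation, TGF-beta response, chemokine receptors and integrins, and T cell identity. Each was tested with camera at a preset correlation of 0.01, adjusted over 135 tests, with an estimated correlation and with fry. Members were also adjusted over the list alone. The residency and circulation scores are the mean log2(TPM + 1) of a list per library, compared by exact two-sided permutation, with the smaller tail doubled. Another 11 lists mark other cell types, and their TPM were summed per library.

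Genes are named by a rule fixed with the lists. It takes 14 core genes, of which 1 is not reported here, and the 8 largest changes in each direction among called genes with a mean log2 of at least 3 and no overlap between the groups. Predicted genes, receptor and immunoglobulin segments and marker genes were left out of these. It also takes up to 4 called members of each list by size of change, of which the report prints a part for length.

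Alternatives set in the design were no filter, a filter of 5 TPM (12471 genes), a pseudocount of 0.1, only the 2 groups compared, array weights, a replicate block and leaving out each library. Added after the values were seen were weights per group, a fit without the 6 libraries whose T cell identity sum was under 0.5 of the median, T cell identity as a covariate, quantile normalization, and rescaling after removal of mitochondrial, repeat and marker genes. The removed libraries were spleen replicate 4, skin replicate 4, liver replicates 2, 3 and 4, and tumor replicate 4.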

Results

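Gene expression was measured by bulk RNA sequencing of CD8+ Thy1.1+ Pmel T cells, which carry a transgenic T cell receptor for a melanocyte antigen, from mice with melanoma-associated vitiligo. The 32 libraries formed 8 groups of 4: naive cells from spleen, cells from the tumor-draining lymph node on day 12, memory cells from the lymph node, and cells from spleen, skin, lung, liver and tumor. The lymph node memory, skin, lung and liver samples were taken 45 days after tumor surgery, and the times of the naive, spleen and tumor samples are not given in the sources used here. The values are TPM, transcript shares scaled to the same sum per library, without read counts, so depth is unknown. Between 10732 genes, in liver replicate 2, and 34211 genes, in skin replicate 4, lay above 0. The labels do not state that each sample came from a separate animal, so the p-values measure only the spread between these samples. Errors of log2 changes are standard errors (SE) of the fit and other errors are standard deviations (SD), with n = 4 libraries per group throughout.

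T cell genes made up an unequal share of the RNA between groups. The 16 genes of the T cell identity list, such as the CD8 and CD3 chains, summed to 41247 ± 3212 TPM in naive cells, 30271 ± 1979 in the day 12 lymph node, 30065 ± 8598 in lymph node memory cells. They summed to 26401 ± 9066 TPM in tumor, 24085 ± 12832 in skin, 21385 ± 8853 in spleen, 20599 ± 4068 in lung and 12131 ± 11047 in liver. Markers of other cells were present beside them. Hepatocyte genes summed to 16191 ± 20763 TPM and erythroid genes to 34559 ± 39492 TPM in liver, against 171 ± 178 and 608 ± 618 TPM in spleen. Myeloid genes summed to 19455 ± 10644 TPM in liver, 9314 ± 9762 in spleen, 8438 ± 5955 in lung, 4742 ± 7983 in skin, 3833 ± 3727 in lymph node memory cells and 49.3 ± 20.9 in naive cells. B cell genes summed to 15021 ± 22094 TPM in lung, 8070 ± 8231 in spleen, 2155 ± 2365 in lymph node memory cells and 79.8 ± 56.5 in skin. Keratinocyte genes reached 3754 ± 3437 TPM in skin and 1201 ± 866 in tumor, and melanocyte and melanoma genes 599 ± 279 in tumor. Lung epithelial genes reached 1210 ± 1567 TPM in lung and 10.2 ± 5.07 in spleen. NK cell genes reached 2708 ± 1628 in liver and 618 ± 509 in spleen, and stromal and endothelial genes 407 ± 354 in skin and 44.0 ± 25.3 in spleen. CD4 and regulatory T cell genes summed to 269 ± 144 TPM in skin and 46.2 ± 15.7 in spleen, and gamma delta T cell genes to at most 65.1 ± 11.5 TPM, in lymph node memory cells.

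**Figure D1:**
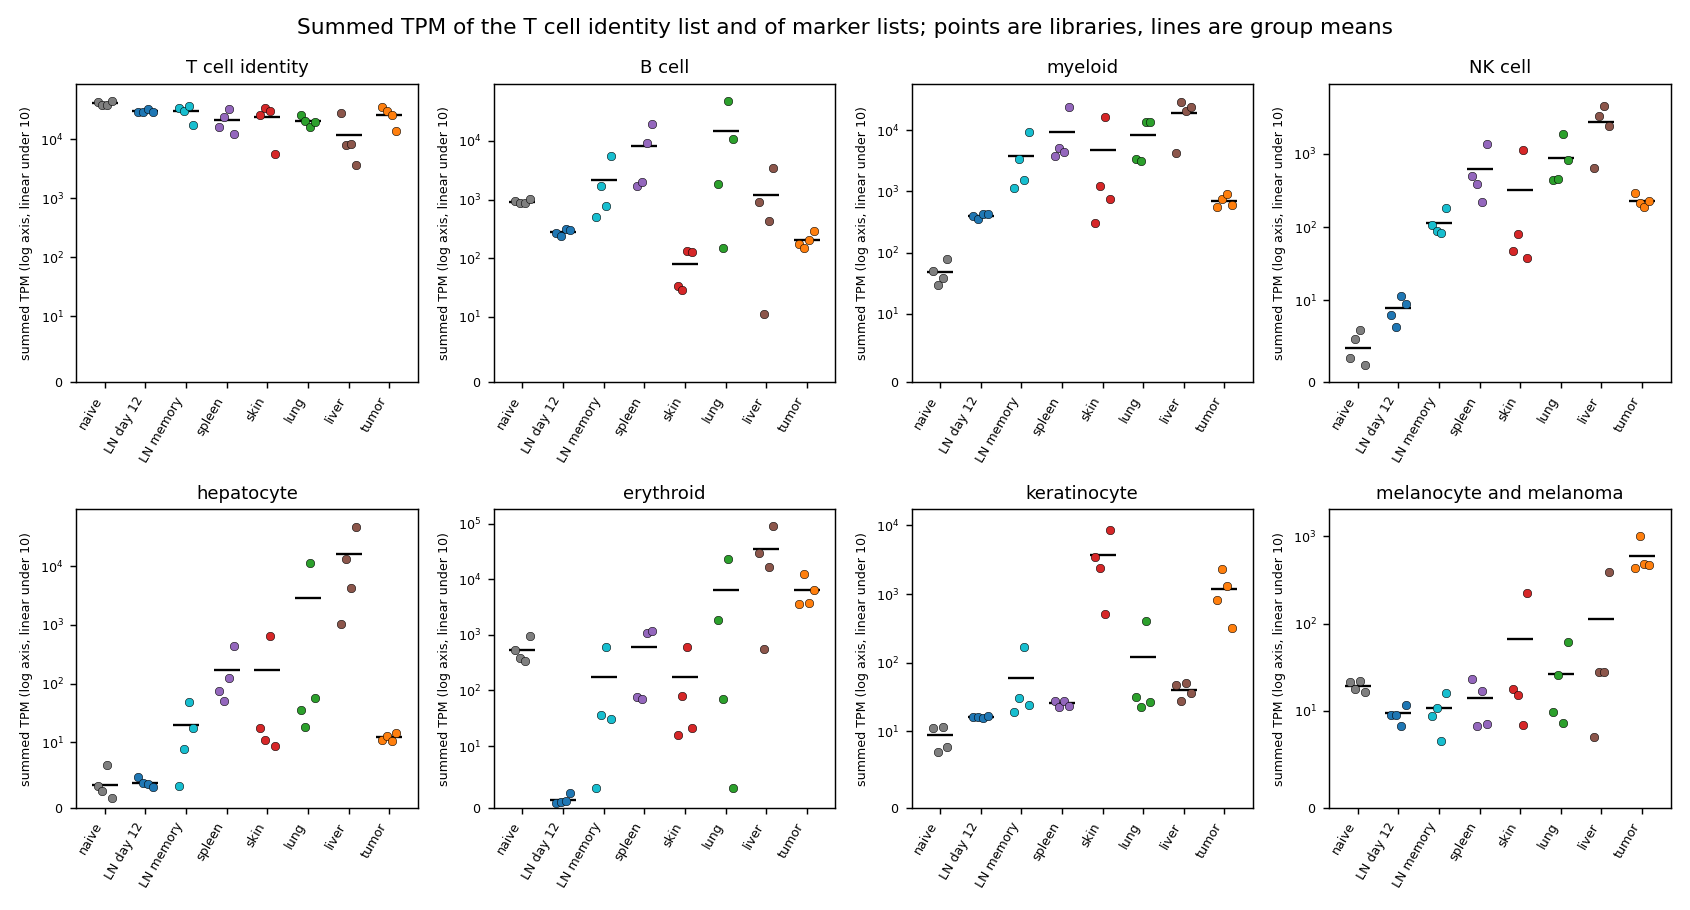
Summed TPM of the T cell identity list and of 7 of the 11 marker lists, each on a log axis that is linear under 10; points are libraries (4 per group) and lines are group means. The T cell identity sum is 3640 TPM in liver replicate 4 and 5650 TPM in skin replicate 4, while the naive libraries lie between 38204 and 44222 TPM.

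Spread within a group was least on day 12 and in naive cells and most in liver. The SE of a gene, pooled over groups, is the same in every comparison, too small for liver and too large for day 12. The SD of the residuals within a group on the log2 scale was 0.303 in the day 12 lymph node, 0.387 in naive cells, 0.512 in tumor, 0.615 in lymph node memory cells, 0.847 in skin, 0.892 in spleen, 0.961 in lung and 1.33 in liver. The first principal component held 24.8% of the variance and ranged from -1.02 to 267.7 in liver and from -71.6 to -56.1 in naive cells. The third component, with 10.3% of the variance, was between -88.4 and -85.1 in the naive libraries and between 26.6 and 72.8 in the skin libraries. Within the mm10 build, the core genes followed below include Itgae on chromosome 11 from 73090583 to 73147446. Cd69 lies on chromosome 6 from 129267325 to 129275436, and Zfp683 on chromosome 4 from 134053838 to 134058996. S1pr1 lies on chromosome 3 from 115710433 to 115715072 and Klf2 on chromosome 8 from 72319033 to 72321656.

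**Figure D2:**
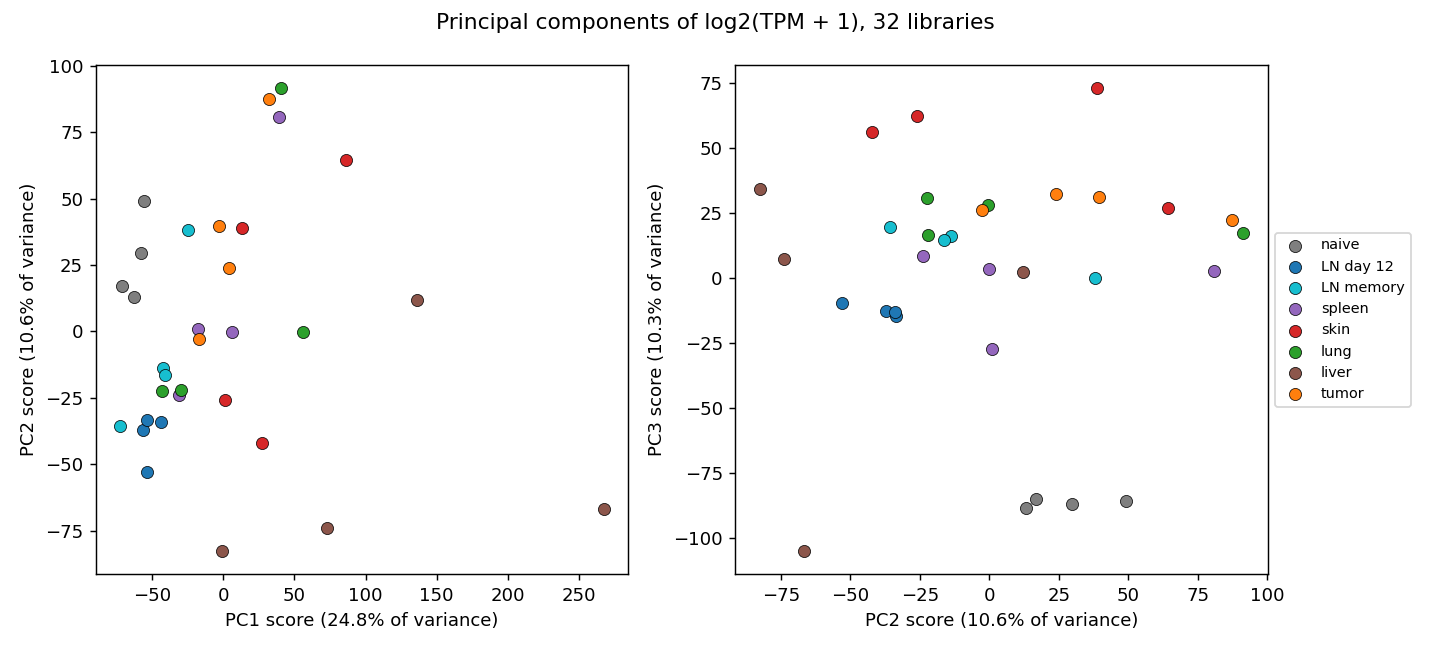
Scores of the 32 libraries on the first 3 principal components of log2(TPM + 1), with the percent of variance on each axis; colors are the groups. Naive libraries lie together near the low end of the third component, with liver replicate 2 beyond them, and liver libraries spread along the first.

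The comparison of skin with spleen asks what sets the cells of the skin, the tissue of the vitiligo, apart from those of a lymphoid organ. Skin libraries held more RNA of genes tied to tissue residency and acute stimulation. Itgae, the integrin chain that binds epithelial E-cadherin, rose by 2.37 ± 0.61 log2 (adjusted p = 0.0121), from 70.8 ± 48.4 to 381 ± 207 TPM, with 3 of the 4 skin libraries above every spleen library. Cd69, which keeps T cells from leaving tissue, rose by 3.67 ± 0.46 (adjusted p = 2.62e-06), from 58.7 ± 33.7 to 722 ± 396 TPM. Zfp683, which encodes the residency factor Hobit, rose by 2 ± 0.56 (adjusted p = 0.0222), with 3 skin libraries above every spleen library. S1pr1, the receptor that guides cells out of tissue, fell by 5.07 ± 0.88 (adjusted p = 0.000241) and its activator Klf2 by 3.82 ± 0.46 (adjusted p = 1.1e-06), each without overlap between the groups. Ifng rose by 6.16 ± 0.59 log2 to 1812 ± 1090 TPM (adjusted p = 2.46e-08) and the inhibitory receptor gene Pdcd1 by 3.53 ± 0.76 (adjusted p = 0.00257). Itga1 (1.55 ± 0.66, adjusted p = 0.177), Cxcr6 (0.32 ± 0.49), Ccr7 (-2.87 ± 1.24, adjusted p = 0.185), Tcf7 (-1.09 ± 0.61), Gzmb (-0.01 ± 0.55) and Mki67 (-0.06 ± 0.44) did not pass the test.

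**Figure D3:**
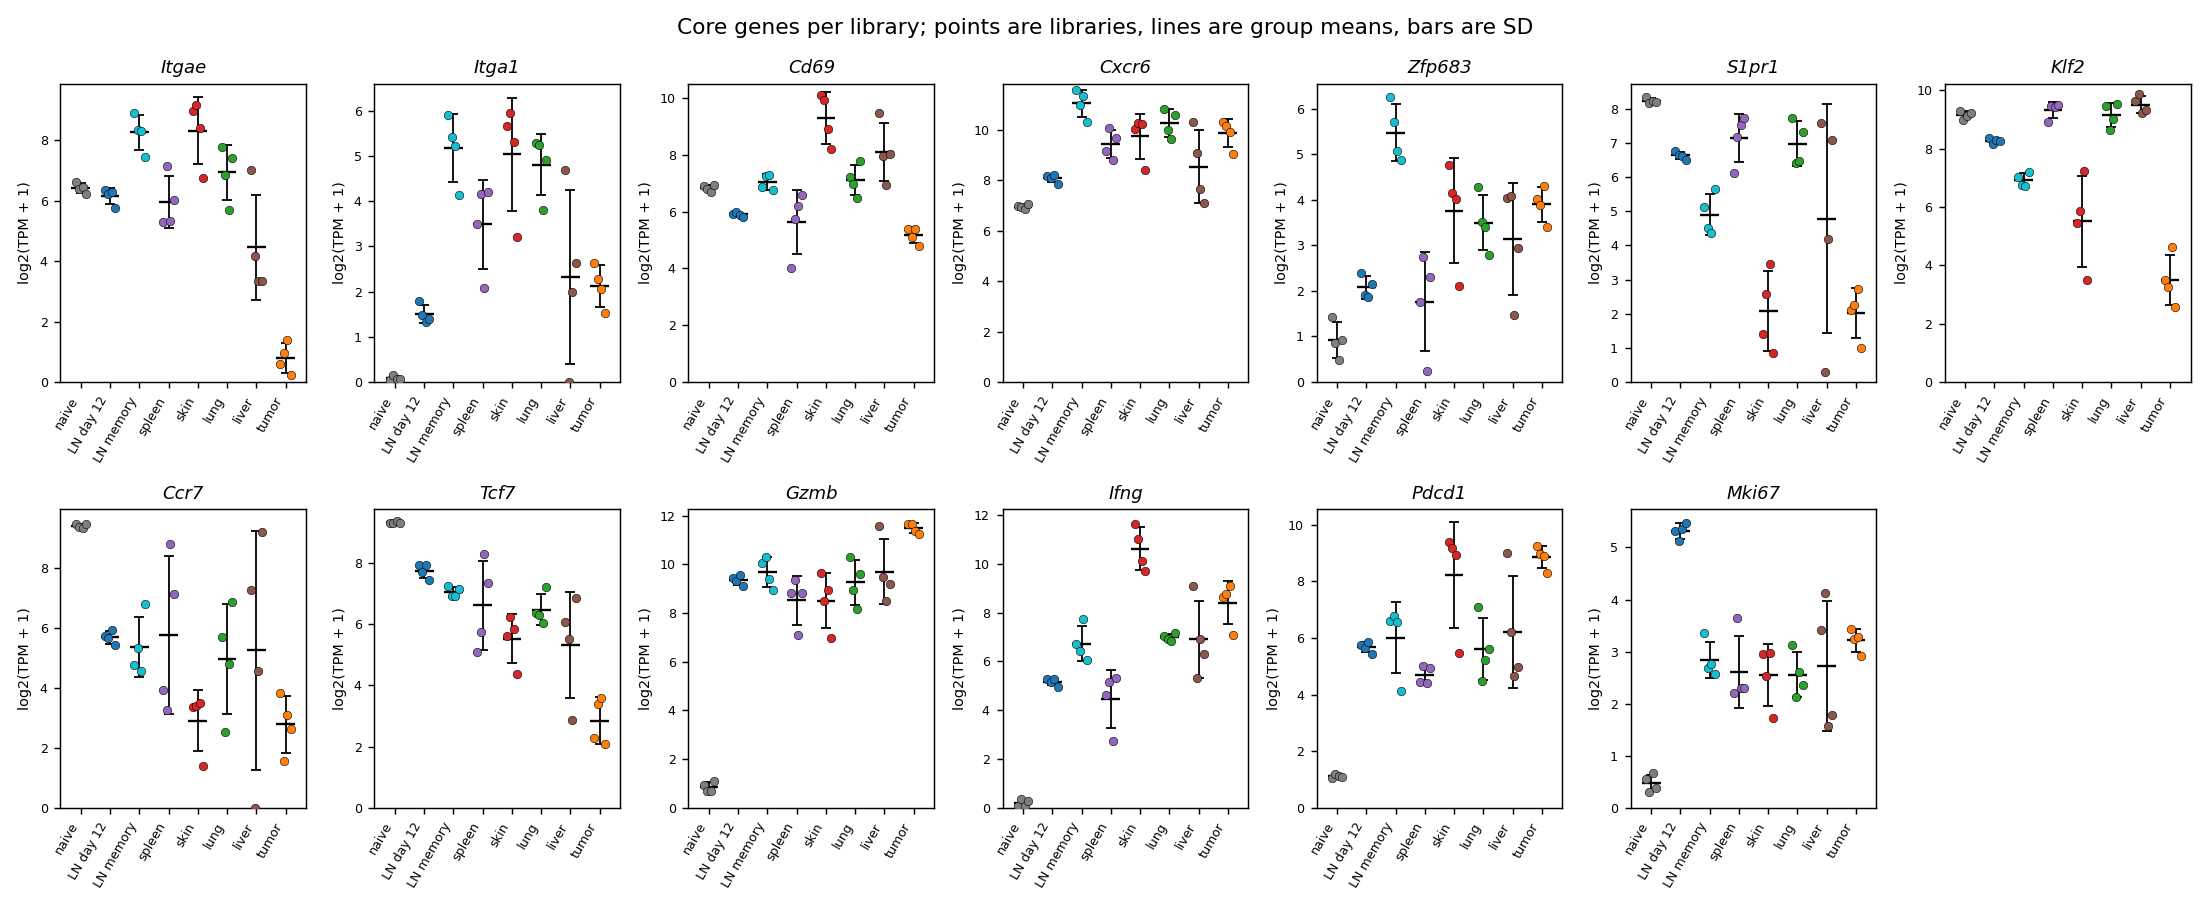
log2(TPM + 1) of 13 core genes in every library; points are libraries (4 per group), lines are group means and bars are SD. Cd69 averages 722 TPM in skin and 58.7 TPM in spleen, and Itgae averages 0.81 TPM in tumor and 325.5 TPM in lymph node memory cells.

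The largest increases in skin over spleen were those of Ccl1, a chemokine gene (8.14 ± 1.08 log2), Fos (7.57 ± 0.90), Nr4a1 (7.48 ± 0.81), the inducible heat shock genes Hspa1b (7.44 ± 1.13) and Hspa1a (7.14 ± 1.11), Atf3 (6.82 ± 0.73), Nr4a2 (6.47 ± 0.70) and the phosphatase gene Dusp1 (6.47 ± 0.77). Their adjusted p lay between 1.65e-07 and 5.75e-05, with no overlap between the groups. Large decreases besides that of S1pr1 were those of Gimap7 (-6.13 ± 0.78), Slpi (-5.90 ± 1.35), Dtx1 (-4.97 ± 0.46), H2-Ob (-4.77 ± 0.87), Slamf6 (-4.52 ± 0.93) and Ly6c2 (-4.46 ± 1.22), with adjusted p between 1.38e-08 and 0.0199. Of the 39 measured members of the residency list, 23 rose and 0 fell (31 and 0 adjusted over the list alone), with a mean change of 2.52 log2 (adjusted p = 2.25e-33, and adjusted p = 0.0206 with an estimated correlation). They included Cdh1, which encodes E-cadherin (4.97 ± 0.55), and Rgs2 (4.68 ± 0.43). Keratinocytes express Cdh1 too, and keratinocyte genes summed to 3754 TPM in skin and 25.5 TPM in spleen. Of the 31 circulation genes 16 fell and 0 rose (18 and 0 adjusted over the list alone), with a mean of -2 log2 (adjusted p = 4.4e-13, and adjusted p = 0.164 with an estimated correlation). Of the 35 immediate early genes, which switch on within minutes of stimulation, 33 rose and 0 fell (33 and 0 adjusted over the list alone), with a mean of 3.82 log2 (adjusted p = 5.68e-63, and adjusted p = 0.00252 with an estimated correlation). Of the 21 genes of the TGF-beta response 10 rose and 0 fell (14 and 0 adjusted over the list alone), among them Rgs16 (4.24 ± 0.74) and Spsb1 (3.86 ± 0.51), with a mean of 1.91 log2 (adjusted p = 1.3e-14, and adjusted p = 0.0392 with an estimated correlation). Without the 5 members it shares with the immediate early list, the residency list kept a mean of 2.10 log2 (34 genes, adjusted p = 7.67e-24).

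The next 7 lists passed the test with the preset correlation and not with an estimated one, whose adjusted p is given for each. By fry, heat shock (adjusted p = 0.00106), naive and central memory (0.0218), type I interferon (0.0164) and glycolysis genes (0.0183) passed and the other 3 did not. Of the 16 heat shock genes 10 rose in skin (12 adjusted over the list alone; mean 2.19 log2, adjusted p = 0.127). Of the 31 cytotoxic effector genes 7 rose and 2 fell (11 and 2 adjusted over the list alone; mean 0.88 log2, adjusted p = 0.468). Ccl3 was up by 4.97 ± 0.82 and Tnf by 4.69 ± 0.57. Of the 22 naive and central memory genes 9 fell (10 adjusted over the list alone; mean -1.61 log2, adjusted p = 0.296). Of the 26 inhibitory receptor and exhaustion genes 5 rose and 1 fell (5 and 1 adjusted over the list alone; mean 1.03 log2, adjusted p = 0.461), including Nr4a3 (4.93 ± 0.47). Of the 26 glycolysis and hypoxia genes 8 rose (9 adjusted over the list alone; mean 1.10 log2, adjusted p = 0.216), led by Hilpda, a lipid droplet protein gene (3.62 ± 0.50). Of the 25 type I interferon genes 2 fell (9 adjusted over the list alone; mean -1.08 log2, adjusted p = 0.285), Ifit3 by 2.19 ± 0.50 and Dhx58 by 1.60 ± 0.47. Of the 36 oxidative phosphorylation genes 1 fell, Sdhb (-0.90 ± 0.26; 0 adjusted over the list alone; mean -0.36 log2, adjusted p = 0.641). The fatty acid carrier genes Fabp4 (3.86 ± 0.62) and Fabp5 (2.92 ± 0.82) were the 2 of 20 lipid uptake and oxidation genes that rose, and this list did not pass (3 adjusted over the list alone; mean 0.63 log2, adjusted p = 0.0549). Fabp5 was highest, at 703.7 TPM, in skin replicate 4, which held the most keratinocyte RNA (8560 TPM). Of 32 chemokine receptor and integrin genes 3 rose and 6 fell (3 and 9 adjusted over the list alone; mean -0.64 log2, adjusted p = 0.198). By limma's test 0 of the 39 proliferation genes (0 adjusted over the list alone; mean 0.21 log2, adjusted p = 0.156) and 0 of the 16 T cell identity genes (0 adjusted over the list alone; mean -0.15 log2, adjusted p = 0.754) passed.

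In all, 855 genes were higher and 660 lower in skin than in spleen, and 9.09% of genes separated the groups without overlap against 2.86% by chance, with a median change of -0.121 log2. Of the 34 called genes named here, 31 stayed called with weights per group, 23 in a fit of only the 2 groups and 28 whichever library was left out. Itgae reached adjusted p = 0.0521 and 0.0525 without skin replicates 1 and 2, and 0.124 in the fit of 2 groups. Zfp683 reached adjusted p = 0.124 without spleen replicate 3, 0.107 and 0.0658 without skin replicates 1 and 2, and 0.0672 with weights per group. Ly6c2 reached adjusted p = 0.0622 without spleen replicate 1, and without skin replicate 4 Ly6c2, Dhx58, Sdhb and Fabp5 reached 0.109, 0.18, 0.13 and 0.126, their highest values. Itga1 passed without skin replicate 4 (2.16 log2, adjusted p = 0.0431). The fit of 2 groups also lost Pdcd1, Ccl3, Ifit3, Hspa1b and Hspa1a (adjusted p = 0.0875, 0.115, 0.231, 0.0594 and 0.0529), and with a replicate block Gimap7 alone of these genes stayed called (adjusted p = 0.021). In the simulation 30 of 137 calls of this fit were false. Without the libraries of low T cell identity the counts were 2183 and 1068, and with only the 2 groups 154 and 117. Without skin replicate 4 alone, 409 genes were lower.

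The comparison of lymph node memory cells with spleen asks which genes set the memory cells of the lymph node apart. Zfp683 rose by 3.71 ± 0.56 log2 (adjusted p = 0.000551), from 3.04 ± 2.32 to 46.7 ± 21.2 TPM, and Klf2 fell by 2.40 ± 0.46 (adjusted p = 0.00842), from 647 ± 111 to 122 ± 19.5 TPM. The largest increases besides Zfp683 were those of Ccl1 (7.08 ± 1.08), Ccl3 (3.60 ± 0.82), Tnf (2.92 ± 0.57), Il2 (2.90 ± 0.69), Dusp6 (2.82 ± 0.59), Chn2 (2.65 ± 0.51) and Ccl4 (2.44 ± 0.53), with adjusted p between 0.000551 and 0.0483. The decreases besides Klf2 were those of Plac8 (-2.63 ± 0.51), Dtx1 (-1.99 ± 0.46), Crip2 (-1.70 ± 0.33) and Acp5 (-1.38 ± 0.30). Itgae (2.31 ± 0.61, adjusted p = 0.0783), Cd69 (1.41 ± 0.46, adjusted p = 0.221), Cxcr6 (1.62 ± 0.49, adjusted p = 0.151) and Ifng (2.27 ± 0.59, adjusted p = 0.0748) missed the threshold, although in each all 4 lymph node libraries lay above all 4 spleen libraries. S1pr1 (-2.24 ± 0.88, adjusted p = 0.359) and Tcf7 (0.44 ± 0.61) did not pass either.

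Of the 39 residency genes 5 rose in lymph node memory cells over spleen and 0 fell (23 and 0 adjusted over the list alone), with a mean of 1.39 log2 (adjusted p = 1.38e-16, and adjusted p = 0.154 with an estimated correlation). Of the 31 circulation genes 2 fell, Klf2 and Klf3 (3 adjusted over the list alone; mean -0.78 log2, adjusted p = 0.285 with an estimated correlation), and Klf3 fell by 2.42 ± 0.51. Of the 31 cytotoxic effector genes 4 rose (6 adjusted over the list alone; mean 0.67 log2, adjusted p = 0.641 with an estimated correlation). Rgs1, a regulator of chemokine receptor signalling, was the 1 immediate early gene of 35 that rose (2.26 ± 0.44; 7 adjusted over the list alone; mean 0.87 log2, adjusted p = 0.351 with an estimated correlation). Cdh1 was the 1 TGF-beta response gene of 21 (2.59 ± 0.55; 5 adjusted over the list alone; mean 0.91 log2, adjusted p = 0.285 with an estimated correlation). No member passed limma's test in 4 further lists that passed with the preset correlation. These were inhibitory receptors (mean 0.60 log2), proliferation (0.49), glycolysis (0.47) and T cell identity (0.53), and none held with an estimated correlation. Naive and central memory genes (mean -0.27 log2), type I interferon genes (0.40), heat shock genes (0.41) and oxidative phosphorylation genes (-0.04) did not pass. Nor did lipid genes (mean -0.03, median 0.11 log2) and chemokine receptors (mean 0.16, median -0.03 log2). In all, 71 genes were higher and 24 lower in lymph node memory cells than in spleen, with 5.39% of genes separating the groups against 2.86% by chance. The median change was 0.166 log2, and the share of higher genes among those called went from 74.7% to 63% with quantile normalization. Of the 16 called genes named here, all 16 stayed called with weights per group and 2 (Ccl1 and Klf2) in a fit of only the 2 groups, where Zfp683 had adjusted p = 0.125. Whichever library was left out, 5 stayed called. Without lymph node memory replicate 2 the adjusted p of Ccl3, Il2, Dusp6, Ccl4, Dtx1, Acp5 and Klf3 was 0.135, 0.172, 0.09, 0.12, 0.143, 0.0912 and 0.107, and that of Crip2 0.0666. Without lymph node memory replicate 1 it was 0.0561 for Plac8, 0.0518 for Rgs1 and 0.113 for Cdh1, and without spleen replicate 3 it was 0.0561 for Rgs1. Itgae passed with weights per group, quantile normalization, rescaling and the covariate (adjusted p = 0.021, 0.024, 0.0457 and 0.0483), Ifng with weights and rescaling (0.0304 and 0.0457) and Cxcr6 with quantile normalization (0.043). Ifng passed without spleen replicate 4 (2.55 log2, adjusted p = 0.0425). The total of 95 genes became 43 or 40 without lymph node memory replicate 1 or 2, and 172 without spleen replicate 4. Spleen libraries held more B cell and myeloid RNA. Without the libraries of low T cell identity of any group the counts were 2017 and 286. Weights per group gave 120 and 68, and a fit of only the 2 groups 3 and 1, with 1916 genes at an unadjusted p under 0.05 in the fit of all groups.

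The comparison of lung with spleen called 10 genes higher and 12 lower among 1457 genes at an unadjusted p under 0.05, and 1.82% of genes separated the groups against 2.86% by chance. Rgs1 rose by 2.53 ± 0.44 log2 (adjusted p = 0.00726), from 39.8 to 192 TPM, and Cdkn1a, a cell cycle inhibitor gene, by 2.22 ± 0.46 (adjusted p = 0.0383), both without overlap between the groups. Ifng (2.53 ± 0.59, adjusted p = 0.0768), Zfp683 (1.74 ± 0.56, adjusted p = 0.313), Cd69 (1.49 ± 0.46, adjusted p = 0.307) and Itgae (0.99 ± 0.61, adjusted p = 0.811) missed the threshold. S1pr1 (-0.16 ± 0.88) and Klf2 (-0.16 ± 0.46) lay close to their spleen levels relative to their errors. Of the 39 residency genes 1 rose, Rgs1 (8 adjusted over the list alone), with a mean of 0.99 log2 (adjusted p = 4.78e-14, and adjusted p = 0.164 with an estimated correlation). By fry this list alone passed in lung (adjusted p = 0.0377). The immediate early list had a mean of 0.99 log2 (1 of 35 rose, 10 adjusted over the list alone; adjusted p = 0.191 with an estimated correlation). The cytotoxic effector list had a mean of 0.61 log2 (0 of 31 rose, 2 adjusted over the list alone; adjusted p = 0.468 with an estimated correlation) and the naive and central memory list of -0.70 log2 (0 of 22 fell; adjusted p = 0.461 with an estimated correlation). Heat shock (mean 0.63 log2), glycolysis (0.39) and TGF-beta response genes (0.52, 1 of 21 higher adjusted over the list alone) passed with the preset correlation and none of them with an estimated one. The circulation list had a mean of -0.20 log2 (adjusted p = 0.119), and the remaining lists, with means between -0.07 and 0.46 log2, did not pass. Lung libraries held 15021 TPM of B cell genes and lung replicate 3 held 11430 TPM of hepatocyte genes. In the simulation 54 of 159 calls of this fit were false. Weights per group gave 4 and 2 genes (Rgs1 at adjusted p = 0.124), and a fit of only the 2 groups gave 0 with limma, with 690 genes at an unadjusted p under 0.05. Cdkn1a lost its call when any 1 lung replicate or spleen replicate 3 or 4 was left out, with the highest adjusted p of 0.111 without spleen replicate 3. Ifng passed without spleen replicate 4 (2.81 log2, adjusted p = 0.0492), with rescaling (0.0461) and with the covariate (0.0309). The total of 22 genes became 56 or 35 without lung replicate 1 or 4, and 44, 37 or 49 without spleen replicate 1, 2 or 4. Without the libraries of low T cell identity 650 genes were higher and 244 lower.

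Liver libraries had higher levels of immediate early genes than spleen libraries. Fos rose by 6.98 ± 0.90 log2, Atf3 by 6.63 ± 0.73, Dusp1 by 6.02 ± 0.77, Nr4a1 by 5.90 ± 0.81, the chemokine gene Ccl3 by 5.84 ± 0.82, Egr1 by 5.40 ± 0.76 and Nr4a2 by 4.89 ± 0.70. Their adjusted p lay between 1.58e-06 and 4.94e-05, with no overlap between the groups. Cd69 rose by 2.47 ± 0.46 log2 (adjusted p = 0.0012), from 58.7 to 335 TPM, and Ifng by 2.44 ± 0.59 (adjusted p = 0.00797). Apoc1, an apolipoprotein gene of hepatocytes and macrophages, rose by 7.13 ± 1.48 (adjusted p = 0.00275) beside the hepatocyte and myeloid RNA of these libraries. Of the 35 immediate early genes 27 rose and 0 fell (30 and 0 adjusted over the list alone), with a mean of 2.92 log2 (adjusted p = 4.86e-60, and adjusted p = 0.00252 with an estimated correlation). Itgae (-1.49 ± 0.61, adjusted p = 0.088), Zfp683 (1.37 ± 0.56, adjusted p = 0.0882), S1pr1 (-2.36 ± 0.88, adjusted p = 0.0669) and Klf2 (0.19 ± 0.46) did not pass the test. The largest decreases were those of Snora57 (-3.50 ± 0.61), Commd5 (-3.45 ± 0.38), Snhg20 (-3.33 ± 0.59), Zfp637 (-3.25 ± 0.53), Rpl36a-ps2 (-3.05 ± 0.60), AI467606 (-3.02 ± 0.52), Fam189b (-2.94 ± 0.80) and Thap3 (-2.92 ± 0.69), with adjusted p between 1.58e-06 and 0.0172.

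Of the 39 residency genes 12 rose and 1 fell in liver (13 and 3 adjusted over the list alone; mean 0.89 log2, adjusted p = 0.175 with an estimated correlation). The list p values that follow also use an estimated correlation. Without the members shared with the immediate early list the mean was 0.38 log2. Of the 31 cytotoxic effector genes 7 rose and 1 fell (7 and 1 adjusted over the list alone; mean 0.55, median -0.02 log2; adjusted p = 0.296), with Ccl4 up by 3.78 ± 0.53. Of 26 inhibitory receptor genes 6 rose and 1 fell (7 and 3 adjusted over the list alone; mean 0.59, median -0.01 log2; adjusted p = 0.296). Of 20 lipid genes 4 rose (4 adjusted over the list alone; mean 0.59 log2, adjusted p = 0.191), led by Fabp1, a fatty acid carrier gene of hepatocytes (6.54 ± 1.19). Of 16 heat shock genes 2 rose (2 adjusted over the list alone; mean 0.75 log2, adjusted p = 0.285). Of 26 glycolysis genes 2 rose (1 adjusted over the list alone; mean 0.01, median -0.19 log2; adjusted p = 0.641), led by Hilpda (3.95 ± 0.50). The proliferation list passed as up with a mean of -0.05 and a median of 0.05 log2 (2 of 39 fell, 1 adjusted over the list alone; adjusted p = 0.711). Of 16 T cell identity genes 2 fell (8 adjusted over the list alone; mean -1.09 log2, adjusted p = 0.711). Circulation (4 of 31 fell, mean -1.03 log2), naive and central memory (1 rose and 3 fell of 22, mean -1.05), interferon (1 of 25 fell, mean -0.15), oxidative phosphorylation (2 of 36 fell, mean -0.38), TGF-beta response (2 rose and 1 fell of 21, mean -0.11) and chemokine receptor genes (1 rose and 1 fell of 32, mean -0.61) did not pass. The interferon, TGF-beta and chemokine receptor lists had a test direction of up against a negative mean. The fit called 484 genes higher and 2197 lower, with a median change of -0.53 log2 over all genes, and quantile normalization, which removes that shift, gave 874 and 707. In the simulation 383 of 495 calls of this fit were false, and 2 of 64 with weights per group. On real data those weights gave 138 higher and 46 lower. A fit of only the 2 groups gave 0 genes with limma, with 2199 at an unadjusted p under 0.05. Of the 21 called genes named for liver, 15 stayed called with weights per group and all 21 whichever library was left out. Those lost with weights per group were Ifng (adjusted p = 0.186), Apoc1 (0.0982), Snora57 (0.156), Rpl36a-ps2 (0.103), Fam189b (0.0982) and Thap3 (0.072). Itgae passed without liver replicate 1 (-2.35 log2, adjusted p = 0.00172), Zfp683 without replicate 3 (1.92 log2, adjusted p = 0.0211), with quantile normalization (0.0349) and with the covariate (0.0329), and S1pr1 without replicate 1 or 4 (adjusted p = 0.00554 and 0.0182). Without liver replicate 1, 2 or spleen replicate 3 the total of 2681 genes became 5351, 1214 or 1717. Without the libraries of low T cell identity only 1 liver library was left.

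**Figure D4:**
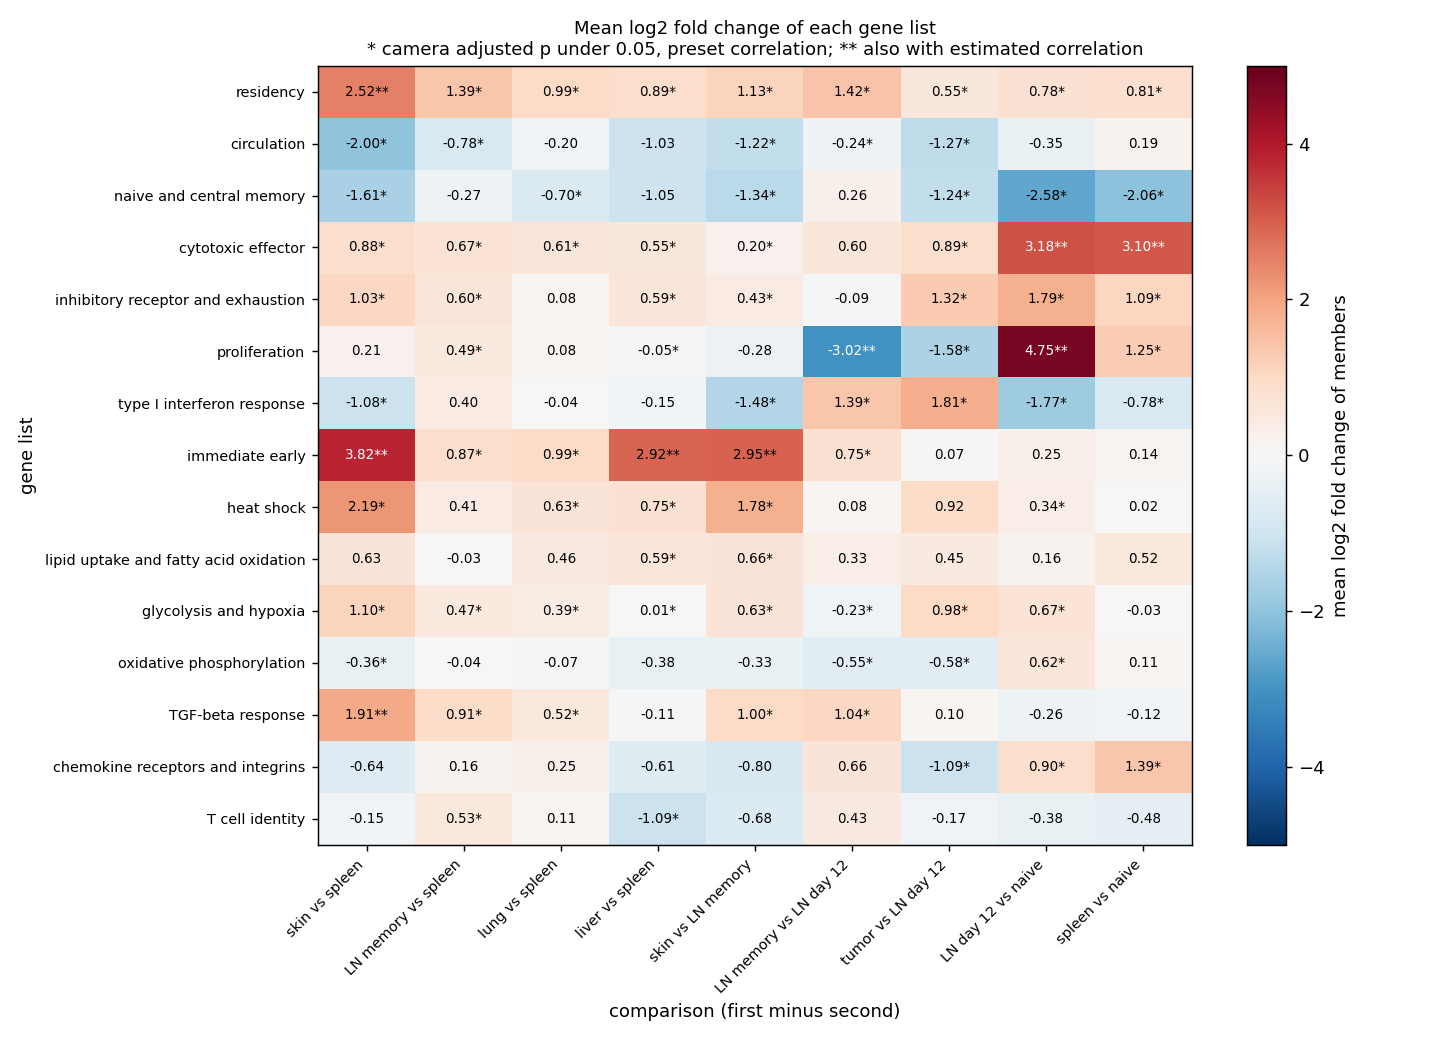
Mean log2 fold change of the members of each of the 15 gene lists (vertical) in each of the 9 comparisons (horizontal, first group minus second). A single asterisk marks an adjusted p under 0.05 by camera with the preset correlation and a double one also with an estimated correlation. The immediate early list has a mean of 3.82 in skin and 2.92 in liver against spleen, and the proliferation list 4.75 in the day 12 lymph node against naive cells.

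Compared directly with lymph node memory cells, skin libraries held more immediate early RNA. Itgae (0.06 ± 0.61), Itga1 (-0.14 ± 0.66) and Mki67 (-0.29 ± 0.44) did not differ by more than their errors. Zfp683 (-1.71 ± 0.56, adjusted p = 0.0556), Cxcr6 (-1.30 ± 0.49, adjusted p = 0.103), Klf2 (-1.42 ± 0.46, adjusted p = 0.0541) and Pdcd1 (2.22 ± 0.76, adjusted p = 0.0689) missed the threshold. Cd69 was higher in skin by 2.26 ± 0.46 log2 (adjusted p = 0.00225) and Ifng by 3.89 ± 0.59 (adjusted p = 6.42e-05). S1pr1 (-2.83 ± 0.88, adjusted p = 0.0444) was lower, without overlap. The largest increases were those of Hspa1a (7.22 ± 1.11), Fos (6.87 ± 0.90), Hspa1b (6.85 ± 1.13), Atf3 (6.19 ± 0.73), Nr4a1 (5.66 ± 0.81), Dusp1 (5.40 ± 0.77), Mgst1 (5.24 ± 1.13) and Apoc1 (5.12 ± 1.48), with adjusted p between 1.88e-06 and 0.0299. Large decreases were those of Gimap7 (-4.94 ± 0.78), Ifit1bl1 (-4.82 ± 0.50), Slamf6 (-4.03 ± 0.93), BC094916 (-3.79 ± 0.62), Gimap4 (-3.70 ± 0.40), BC147527 (-3.68 ± 0.68) and H2-Ob (-3.66 ± 0.87), with adjusted p between 2.1e-07 and 0.00779.

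Of the 35 immediate early genes 28 were higher in skin than in lymph node memory cells and 0 lower (31 and 1 adjusted over the list alone; mean 2.95 log2, adjusted p = 4.94e-51, and adjusted p = 0.00328 with an estimated correlation). Residency genes were higher in 13 of 39 (16 higher and 2 lower adjusted over the list alone; mean 1.13 log2, adjusted p = 0.191 with an estimated correlation), and without the members shared with the immediate early list their mean was 0.76 log2. The list p values that follow also use an estimated correlation. Of 25 type I interferon genes 9 were lower (17 adjusted over the list alone; mean -1.48 log2, adjusted p = 0.189). Ifit3 was lower by 3.39 ± 0.50. Of 16 heat shock genes 6 were higher (10 higher and 1 lower adjusted over the list alone; mean 1.78 log2, adjusted p = 0.157). Of 21 TGF-beta response genes 9 were higher (9 adjusted over the list alone; mean 1 log2, adjusted p = 0.189), led by Tgif1 (2.94 ± 0.51). Of 31 circulation genes 8 were lower (1 higher and 16 lower adjusted over the list alone; mean -1.22 log2, adjusted p = 0.476). Of 22 naive and central memory genes 4 were lower (9 adjusted over the list alone; mean -1.34 log2, adjusted p = 0.499), including Il7r (-2.88 ± 0.42) and Ltb (-2.81 ± 0.45). The cytotoxic effector (mean 0.20 log2, adjusted p = 0.731), inhibitory receptor (mean 0.43, median -0.04 log2, adjusted p = 0.686), lipid (mean 0.66, median -0.02 log2, adjusted p = 0.335) and glycolysis lists (mean 0.63 log2, adjusted p = 0.353) passed with the preset correlation only. Proliferation (mean -0.28 log2), oxidative phosphorylation (-0.33), chemokine receptor (-0.80) and T cell identity genes (-0.68) did not pass. Keratinocyte genes summed to 3754 TPM in skin and 60.5 TPM in lymph node memory cells, and stromal and endothelial genes to 407 and 45.9 TPM. In all, 627 genes were higher and 850 lower in skin, with 20.6% of genes separating the groups, and the median change was -0.25 log2. Quantile normalization raised the share of higher genes among those called from 42.5% to 55.9%. Of the 22 called genes named here, all 22 stayed called with weights per group and in a fit of the 2 groups, and 20 whichever library was left out. S1pr1 lost its call when any 1 library except skin replicate 3 was left out, up to adjusted p = 0.168 without skin replicate 4. Apoc1 reached adjusted p = 0.11 without skin replicate 4, and 0.101 and 0.103 without lymph node memory replicates 1 and 2. With weights per group Zfp683, Cxcr6, Klf2 and Pdcd1 passed (adjusted p = 0.0298, 0.035, 0.037 and 0.0217), Cxcr6 also with quantile normalization (0.0404) and Pdcd1 with that, rescaling and the covariate (0.00819, 0.0296 and 0.000163). Zfp683 passed without skin replicate 1 (adjusted p = 0.0374), Klf2 without skin replicate 3 (0.00198) and Pdcd1 without skin replicate 4 (0.00507). The counts were 1011 and 1539 without the libraries of low T cell identity. The total of 1477 became 823 or 877 without lymph node memory replicate 1 or 2. Without skin replicate 4 the balance turned, with 560 genes higher and 390 lower.

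Lymph node memory cells differed from day 12 lymph node cells, an earlier state in the same organ, by lower cell cycle RNA. Of the 39 proliferation genes 38 fell and 0 rose (39 and 0 adjusted over the list alone), with a mean of -3.02 log2 (adjusted p = 1.77e-64, and adjusted p = 0.00328 with an estimated correlation). Ccnb2 fell by 4.04 ± 0.73, Ccna2 by 4.01 ± 0.72 and Mki67 by 2.48 ± 0.44 (adjusted p = 0.000397). Itga1 rose by 3.67 ± 0.66 log2 (adjusted p = 0.000463), Zfp683 by 3.40 ± 0.56 (adjusted p = 0.000173), Cxcr6 by 2.97 ± 0.49 (adjusted p = 0.000167) and Itgae by 2.10 ± 0.61 (adjusted p = 0.0296), each without overlap. Cd69 (1.14 ± 0.46, adjusted p = 0.142), S1pr1 (-1.73 ± 0.88) and Gzmb (0.33 ± 0.55) did not pass. Of the 39 residency genes 13 rose and 0 fell (17 and 1 adjusted over the list alone; mean 1.42 log2, adjusted p = 0.296 with an estimated correlation). Of 25 type I interferon genes 9 rose (15 adjusted over the list alone; mean 1.39 log2, adjusted p = 0.206 with an estimated correlation). Ifit3 was up by 3.70 ± 0.50. The largest increases were those of Snord13 (5.44 ± 1.07), Csf1 (5.36 ± 0.63), 4 transcripts with identical values, Rnu3b1, Rnu3b3, ACEA.1 and ACEA.4 (5.17 ± 1.32), Ly6g5b (4.94 ± 0.65) and Metrnl (4.79 ± 0.39), with adjusted p between 1.63e-09 and 0.0131. The largest decreases besides the cyclins were those of AL589651.4 (-6.68 ± 0.91), Zbtb32 (-4.41 ± 0.50), Birc5 (-3.83 ± 0.59), Ccnb1 (-3.83 ± 0.86) and the transcripts AC034285.2 and AL592149.1 (-3.80 ± 0.60).

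In the same comparison of the lymph node at both times, 5 of 22 naive and central memory genes rose (5 and 1 lower adjusted over the list alone; mean 0.26 log2, adjusted p = 0.812), led by the interleukin receptor gene Il7r (3.41 ± 0.42). Cytotoxic effector genes rose in 9 of 31 cases and fell in 1 (10 and 3 adjusted over the list alone; mean 0.60 log2, adjusted p = 0.145). Gzmf changed by -3.96 ± 0.28 and Ccl5 by 3.23 ± 0.65. Immediate early genes (5 of 35 rose, 6 adjusted over the list alone; mean 0.75 log2, adjusted p = 0.628 with an estimated correlation) passed as higher with the preset correlation. Here the list p values that follow also use an estimated correlation. TGF-beta response genes passed as higher too (6 of 21 rose, 7 adjusted over the list alone; mean 1.04 log2, adjusted p = 0.355). Oxidative phosphorylation genes (3 of 36 fell, 9 adjusted over the list alone; mean -0.55 log2, adjusted p = 0.191) passed as lower. So did glycolysis genes (1 rose and 5 fell of 26, 2 and 5 adjusted over the list alone; mean -0.23 log2, adjusted p = 0.563) and circulation genes (2 of 31 fell, 2 adjusted over the list alone; mean -0.24 log2, adjusted p = 0.711). Inhibitory receptor (mean -0.09 log2), chemokine receptor (0.66), T cell identity (0.43), heat shock (mean 0.08, test direction down) and lipid genes (mean 0.33, test direction down) did not pass. Day 12 libraries held 404 ± 40.7 TPM of myeloid genes, against 3833 in lymph node memory cells. In all, 873 genes were higher and 590 lower, 37.4% of genes separated the groups, and the median change was 0.261 log2. Quantile normalization took the share of higher genes from 59.7% to 37.5%. Of the 25 called genes named here, all 25 stayed called with weights per group and in a fit of the 2 groups, and 20 whichever library was left out. Cd69 and S1pr1 gained calls with weights per group (adjusted p = 7.42e-05 and 0.000131) and with 2 groups (0.000643 and 0.0021), and Cd69 with quantile normalization (0.0425). Itgae reached an adjusted p between 0.0576 and 0.104 when any 1 library except lymph node memory replicate 4 was left out. The transcripts Rnu3b1, Rnu3b3, ACEA.1 and ACEA.4 reached adjusted p = 0.0534 without lymph node memory replicate 2. Weights per group gave 5379 and 2142, and the total of 1463 fell to between 816 and 951 when 1 of day 12 replicates 1, 2 and 3 or lymph node memory replicates 1 and 2 was left out.

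Tumor libraries held much less RNA of Itgae, Tcf7 and Klf2 than those of the draining lymph node on day 12. Itgae fell by 5.37 ± 0.61 log2 (adjusted p = 5e-07), from 71.5 to 0.81 TPM. Tcf7, a factor of naive and memory cells, fell by 4.90 ± 0.61 (adjusted p = 2.57e-06), Klf2 by 4.78 ± 0.46 (adjusted p = 2.41e-08) and S1pr1 by 4.62 ± 0.88 (adjusted p = 0.00105). Pdcd1 rose by 3.17 ± 0.76 (adjusted p = 0.00853), Gzmb by 2.14 ± 0.55 (adjusted p = 0.0152) to 2905 TPM, and Ifng by 3.24 ± 0.59 (adjusted p = 0.00059), while Mki67 fell by 2.10 ± 0.44 (adjusted p = 0.00258). Cxcr6 (1.78 ± 0.49, adjusted p = 0.0215) and Zfp683 (1.82 ± 0.56, adjusted p = 0.0432) passed as well. Cd69 (-0.73 ± 0.46), Itga1 (0.62 ± 0.66) and Ccr7 (-2.91 ± 1.24, adjusted p = 0.161) did not. The largest increases were those of Hspa1a (5.95 ± 1.11), Hspa1b (5.88 ± 1.13), Sbsn (5.69 ± 0.66), Ccl3 (5.68 ± 0.82), Cd63 (5.61 ± 1.07), the receptor gene Lilrb4a (5.38 ± 0.78), Snord13 (5.16 ± 1.07) and Snord118 (5.10 ± 0.99). The largest decreases besides Itgae, Tcf7 and Klf2 were those of H3f3c (-5.70 ± 0.68), Ccr10 (-5.27 ± 0.80), Gzma (-4.83 ± 0.90), Trat1 (-4.75 ± 0.53) and AL589651.4 (-4.72 ± 0.91). The top genes had adjusted p of 0.00249 or less and no overlap.

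Of 26 inhibitory receptor and exhaustion genes 10 rose and 1 fell in tumor (11 and 1 adjusted over the list alone; mean 1.32 log2, adjusted p = 0.325 with an estimated correlation), including Entpd1 (3.93 ± 0.64). The list p values that follow also use an estimated correlation. Of 25 type I interferon genes 12 rose (21 adjusted over the list alone; mean 1.81 log2, adjusted p = 0.0856), led by Usp18 (3.48 ± 0.56). Of 31 cytotoxic effector genes 11 rose and 2 fell (15 and 3 adjusted over the list alone; mean 0.89 log2, adjusted p = 0.488). Of 31 circulation genes 12 fell and 1 rose (2 rose and 15 fell adjusted over the list alone; mean -1.27 log2, adjusted p = 0.285). Of 22 naive and central memory genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; mean -1.24 log2, adjusted p = 0.462). Of 39 proliferation genes 9 fell (33 adjusted over the list alone; mean -1.58 log2, adjusted p = 0.164). Residency genes went both ways, with 10 of 39 up and 4 down (15 and 4 adjusted over the list alone; mean 0.55 log2, adjusted p = 0.752). Of 32 chemokine receptor and integrin genes 3 rose and 10 fell (4 and 13 adjusted over the list alone; mean -1.09 log2, adjusted p = 0.296). Of 26 glycolysis genes 5 rose (5 adjusted over the list alone; mean 0.98 log2, adjusted p = 0.452), led by the hypoxia gene Bnip3 (3.87 ± 0.41). Of 36 oxidative phosphorylation genes 3 fell (7 adjusted over the list alone; mean -0.58 log2, adjusted p = 0.296). Heat shock (mean 0.92, median -0.11 log2), lipid (0.45), T cell identity (-0.17), immediate early (mean 0.07, median -0.17) and TGF-beta response genes (mean 0.10, median -0.11) did not pass. Tumor libraries held 1201 TPM of keratinocyte, 599 of melanocyte and melanoma, 6541 of erythroid (1.31 on day 12) and 229 of NK cell genes (9.04). Their mitochondrial genes held 5.43 to 14.8% of TPM (2.28 to 3.04). Whether keratinocytes or melanoma cells gave Sbsn or Cd63 was not tested. In all, 899 genes were higher and 477 lower, and 42.3% of genes separated the groups. The share of higher genes among those called, 65.3%, was 48.2% with quantile normalization and 75.5% after rescaling. Of the 26 called genes named here, all 26 stayed called with weights per group and in a fit of the 2 groups, and 24 whichever library was left out. Ccr7 and Cd69 gained calls with weights per group (adjusted p = 2.46e-05 and 0.00387) and with 2 groups (0.00121 and 0.0054). Zfp683 lost its call whichever library was left out (adjusted p between 0.0644 and 0.125). Cxcr6 reached adjusted p = 0.0678 without tumor replicate 2 and 0.0634 without day 12 replicate 4. Weights per group gave 4685 and 4252, and 1129 and 1202 genes were called without the libraries of low T cell identity. The total of 1376 fell to between 774 and 868 when any 1 library except tumor replicate 1 was left out.

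Cells of the day 12 lymph node differed from naive spleen cells, in state and in organ, by a coordinated rise of cell cycle and effector genes. All 39 proliferation genes rose (39 adjusted over the list alone), with a mean of 4.75 log2 (adjusted p = 6.14e-73, and adjusted p = 0.00252 with an estimated correlation). Mki67 rose by 4.84 ± 0.44 (adjusted p = 3.2e-09) from 0.395 to 38.98 TPM. Of 31 cytotoxic effector genes 18 rose and 1 fell (23 and 1 adjusted over the list alone), with a mean of 3.18 log2 (adjusted p = 1.76e-26, and adjusted p = 0.023 with an estimated correlation), including the granzyme gene Gzmb (8.49 ± 0.55). Ifng rose by 4.97 ± 0.59 (adjusted p = 3.38e-07) and Pdcd1 by 4.56 ± 0.76 (adjusted p = 6.33e-05). Ccr7 fell by 3.73 ± 1.24 (adjusted p = 0.0483). Itgae (-0.25 ± 0.61), Cd69 (-0.94 ± 0.46), Cxcr6 (1.12 ± 0.49), S1pr1 (-1.60 ± 0.88), Klf2 (-0.88 ± 0.46) and Tcf7 (-1.58 ± 0.61) did not pass. The largest increases besides Gzmb were those of S100a4 (9.43 ± 0.73), Lgals3 (9.21 ± 0.55), S100a6 (9.10 ± 0.57), Anxa2 (7.87 ± 0.51), Ifitm1 (7.85 ± 0.94), the chemokine receptor gene Cxcr3 (7.79 ± 0.49) and Gzmk (7.77 ± 1.04). The largest decreases were those of Igfbp4 (-5.08 ± 0.83), Pik3ip1 (-4.94 ± 0.67), the identical transcripts Rnu3b1, Rnu3b3, ACEA.1 and ACEA.4 (-4.90 ± 1.32), Socs3 (-4.70 ± 0.72) and AL662809.1 (-4.69 ± 0.98). All these had adjusted p of 0.0127 or less and no overlap between the groups.

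In the same comparison with naive cells, 17 of 22 naive and central memory genes fell (20 adjusted over the list alone; mean -2.58 log2, adjusted p = 0.157 with an estimated correlation). The list p values that follow also use an estimated correlation. Type I interferon genes fell in 13 of 25 cases (19 adjusted over the list alone; mean -1.77 log2, adjusted p = 0.164), Ifit3 by 3.83 ± 0.50. Inhibitory receptor genes rose in 10 of 26 cases (13 adjusted over the list alone; mean 1.79 log2, adjusted p = 0.154). Of 36 oxidative phosphorylation genes 9 rose (14 adjusted over the list alone; mean 0.62 log2, adjusted p = 0.285). Of 26 glycolysis genes 6 rose and 2 fell (8 and 3 adjusted over the list alone; mean 0.67 log2, adjusted p = 0.437). Tpi1 was up by 2.93 ± 0.29. Of 32 chemokine receptor and integrin genes 9 rose and 5 fell (9 and 6 adjusted over the list alone; mean 0.90 log2, adjusted p = 0.296), with the gut homing receptor gene Ccr9 down by 7.37 ± 0.76. Of 39 residency genes 10 rose and 3 fell (13 and 4 adjusted over the list alone; mean 0.78 log2, adjusted p = 0.524). A single heat shock gene of 16 rose (1 adjusted over the list alone; mean 0.34 log2, adjusted p = 0.641). Circulation (mean -0.35 log2), immediate early (0.25), lipid (mean 0.16, median -0.06), TGF-beta response (-0.26) and T cell identity genes (-0.38) did not pass. Erythroid genes summed to 546 ± 276 TPM in naive and 1.31 ± 0.76 TPM in day 12 libraries. In all, 1175 genes were higher and 1014 lower, 51.3% of genes separated the groups, and the median change was -0.191 log2. Of the 23 called genes named here, all 23 stayed called with weights per group and in a fit of the 2 groups, and 18 whichever library was left out. Of the 6 named genes not called, all but Itgae passed in both of these fits (adjusted p of 5.2e-05 or less), Tcf7 with quantile normalization (0.0213) and Cxcr6 with the covariate (0.000792). Ccr7 lost its call whichever library was left out (adjusted p between 0.0887 and 0.105). The transcripts Rnu3b1, Rnu3b3, ACEA.1 and ACEA.4 reached adjusted p = 0.0559 without naive replicate 2. With weights per group 3951 and 7250 genes were called, and without naive replicate 1 or day 12 replicate 3 the 1014 lower genes became 647.

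Cells of the spleen group differed from naive spleen cells by higher cytotoxic effector genes. Ccl5, a chemokine gene, rose by 11.90 ± 0.65 log2, Ifitm1 by 10.40 ± 0.94, Lgals3 by 10.30 ± 0.55, S100a4 by 10.20 ± 0.73, S100a6 by 10.10 ± 0.57, the NK receptor gene Klrc1 by 8.48 ± 0.59, Gzma by 7.72 ± 0.90 and Gzmb by 7.67 ± 0.55. Their adjusted p was 8.2e-07 or less, with no overlap. Of 31 cytotoxic effector genes 15 rose and 0 fell (19 and 0 adjusted over the list alone), with a mean of 3.10 log2 (adjusted p = 2.19e-26, and adjusted p = 0.023 with an estimated correlation). Itga1 rose by 3.41 ± 0.66 (adjusted p = 0.00108), Cxcr6 by 2.47 ± 0.49 (adjusted p = 0.00131), Ifng by 4.26 ± 0.59 (adjusted p = 1.09e-05), Pdcd1 by 3.59 ± 0.76 (adjusted p = 0.0027) and Mki67 by 2.14 ± 0.44 (adjusted p = 0.00197). Tcf7 fell by 2.71 ± 0.61 (adjusted p = 0.00499). The largest decreases were those of Rpl38-ps2 (-6.24 ± 1.39), Lef1 (-4.14 ± 0.93), Tdrp (-4.10 ± 0.79), the kinase gene Pdk1 (-3.55 ± 0.64), Satb1 (-3.53 ± 0.71), Socs3 (-3.34 ± 0.72), Nsg2 (-3.26 ± 0.76) and Siah1a (-3.12 ± 0.56), with adjusted p between 0.000435 and 0.00652. Itgae (-0.46 ± 0.61), Cd69 (-1.21 ± 0.46, adjusted p = 0.135) and Ccr7 (-3.64 ± 1.24, adjusted p = 0.0811) did not pass.

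Of 22 naive and central memory genes 9 fell in spleen against naive cells (16 adjusted over the list alone; mean -2.06 log2, adjusted p = 0.166 with an estimated correlation). The list p values that follow also use an estimated correlation. Of 39 proliferation genes 15 rose (17 adjusted over the list alone; mean 1.25 log2, adjusted p = 0.285). Chemokine receptor and integrin genes rose in 11 of 32 cases and fell in 2 (14 and 5 adjusted over the list alone; mean 1.39 log2, adjusted p = 0.164), led by Cxcr3 (6.96 ± 0.49). Inhibitory receptor genes (8 rose and 1 fell of 26, 10 and 1 adjusted over the list alone; mean 1.09 log2, adjusted p = 0.325) passed as higher. Residency genes did so too (11 rose and 3 fell of 39, 14 and 5 adjusted over the list alone; mean 0.81 log2, adjusted p = 0.499). Type I interferon genes passed as lower, with 0 of 25 called by limma (0 adjusted over the list alone; mean -0.78 log2, adjusted p = 0.468). Circulation (mean 0.19, median -0.11 log2), immediate early (0.14), heat shock (mean 0.02, median -0.21), lipid (0.52), glycolysis (mean -0.03, median 0.15), oxidative phosphorylation (0.11), TGF-beta response (-0.12) and T cell identity genes (-0.48) did not pass. B cell genes summed to 926 ± 72.9 TPM, myeloid genes to 49.3 TPM and NK cell genes to 4.17 ± 2.02 TPM in naive libraries, against 8070, 9314 and 618 ± 509 TPM in the libraries of the spleen group. In all, 715 genes were higher and 486 lower, with 19.6% of genes separating the groups. Quantile normalization took the share of higher genes from 59.5% to 48.2%. Of the 23 called genes named here, all 23 stayed called with weights per group, 19 in a fit of the 2 groups and 22 whichever library was left out. Lef1, Tdrp, Socs3 and Nsg2 were lost in the fit of 2 groups (adjusted p = 0.0713, 0.0606, 0.0999 and 0.0775), and Nsg2 reached 0.0521 without spleen replicate 2. Ccr7 passed without spleen replicate 3 (adjusted p = 0.0214) and with weights per group (0.00308), and Cd69 with these weights (0.016) and with quantile normalization (0.0452). With weights per group 1259 and 1261 genes were called, the counts without the libraries of low T cell identity were 1467 and 2881, and the total of 1201 fell to 782 or 797 without naive replicate 1 or 2.

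The mean of the residency list per library was highest in skin, at 6.13 ± 0.90, followed by 5 ± 0.40 in lymph node memory cells, 4.60 ± 0.29 in lung and 4.50 ± 0.86 in liver. It was 4.13 ± 0.30 in tumor, 3.61 ± 0.54 in spleen, 3.58 ± 0.07 in the day 12 lymph node and 2.80 ± 0.08 in naive cells. In exact two-sided permutation tests, whose smallest p for 4 against 4 libraries is 0.0286, 6 differences had p = 0.0286, and 0.0429 after adjustment over the 9 comparisons. The score was higher in skin than in spleen by 2.52, and in lymph node memory than in spleen by 1.39 and than in the day 12 node by 1.42. It was also higher in tumor than in the day 12 node by 0.55, in the day 12 node than in naive cells by 0.78 and in spleen than in naive cells by 0.81. Lung exceeded spleen by 0.99 (exact p = 0.0571, adjusted 0.0735), liver exceeded spleen by 0.89 (exact p = 0.143) and skin exceeded lymph node memory cells by 1.13 (exact p = 0.114). The circulation score was lowest in skin, at 3.10 ± 0.51, and in tumor, at 3.28 ± 0.27. It was 5.10 ± 0.56 in spleen, 4.91 ± 0.06 in naive cells, 4.90 ± 0.81 in lung, 4.56 ± 0.07 in the day 12 node, 4.32 ± 0.25 in lymph node memory cells and 4.06 ± 1.47 in liver. It was lower in skin than in spleen by -2, in skin than in lymph node memory cells by -1.22, in tumor than in the day 12 node by -1.27 and in the day 12 node than in naive cells by -0.35 (exact p = 0.0286 each). None of the 9 differences passed after adjustment, where these 4 reached 0.0643. Differences of -0.78 between lymph node memory and spleen (exact p = 0.0571), -0.20 between lung and spleen (exact p = 0.714), -1.03 between liver and spleen (exact p = 0.286), -0.24 between the lymph node at both times (exact p = 0.143) and 0.19 between spleen and naive cells (exact p = 0.686) did not pass. With 3 libraries left in a group the smallest p of this test, which doubles the smaller tail, is 0.0571, so leaving 1 out gives values only.

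**Figure D5:**
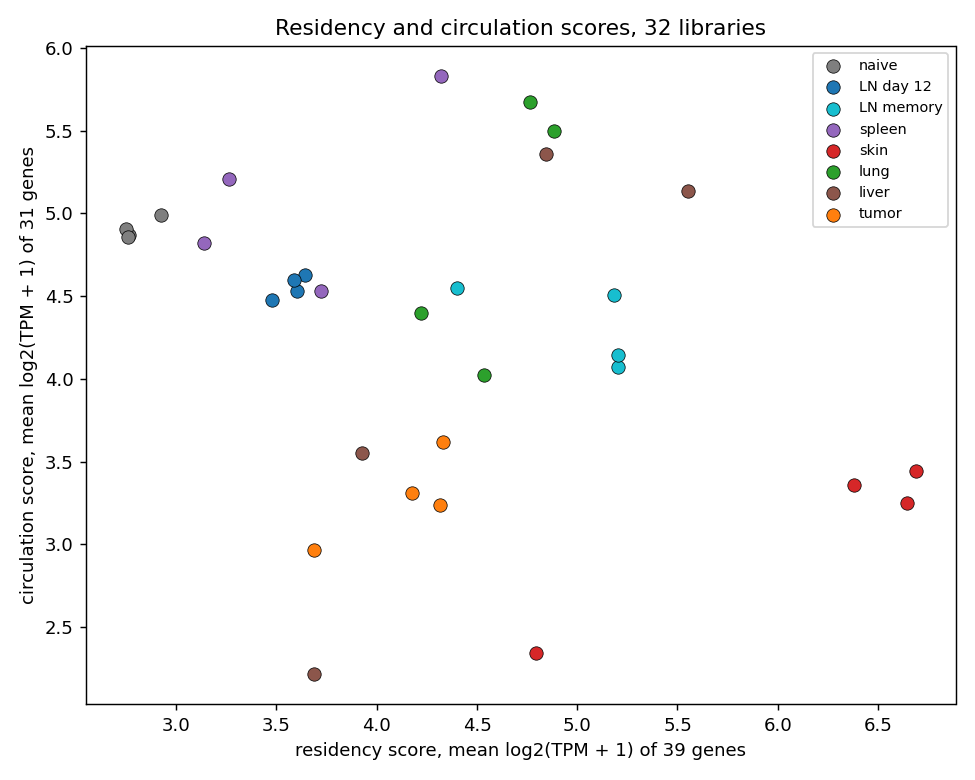
Residency score (horizontal) and circulation score (vertical) of each library, as the mean log2(TPM + 1) of 39 and 31 genes; colors are the groups. The skin libraries have circulation scores between 2.35 and 3.44 and residency scores between 4.80 and 6.69, and the spleen libraries lie between 4.53 and 5.83 and between 3.14 and 4.32.

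Few genes were called alike against spleen in skin, lymph node memory cells, lung and liver. Rgs1 was the 1 gene higher in all 4 and Fcrl5, Gm13532, Hs3st2 and Itgad, named after their values were seen, the 4 lower. Whether the 4 mark other cells of the spleen was not tested. Independent lists would share 3.82e-05 and 5.43e-05 genes and 50 simulated sets without change against shared controls gave 0. Neither keeps the real call numbers with the same spleen libraries, so an excess was not tested. Skin, lymph node memory cells and liver shared 7 higher and 11 lower genes (independent lists 0.0754 and 0.0893), among them Ccl3, Ccl4, Tnf, Chn2 and Dusp6 as higher. Skin and lymph node memory cells shared 41 higher and 23 lower genes (independent lists 3.08 and 0.803), skin and liver 137 and 327 (21 and 73.5) and skin and lung 4 and 10 (0.433 and 0.401). Across genes, which are not independent replicates, the log2 changes of skin and lymph node memory cells correlated at r = 0.443 against the same spleen libraries and at r = 0.128 against separate pairs of spleen libraries. The values were 0.476 and 0.242 for skin and liver, and 0.495 and 0.138 for skin and lung. Simulated groups without change, against shared spleen libraries, gave r = 0.597, 0.402 and 0.494 for skin with lymph node memory cells, liver and lung. Most of the correlation with lymph node memory cells and lung can arise from these libraries. For skin and liver a covariance of 0.475 was 0.286 with separate libraries and 0.198 without any change. The 5 genes shared by all 4 tissues became 12 without spleen replicate 1, 11 without spleen replicate 4, 2 with weights per group and 0 in fits of only the 2 groups by limma.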

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

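The values in this part were singled out by fixed rules, and every test of an explanation was chosen after the result was seen, except the share of genes lower in skin that are near 0 in naive and day 12 libraries.

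A library far from the other 3 of its group, beyond Dixon's 95% critical value, occurred 20 times among 248 groups of values, where chance gives about 12 (1 in 20), in 11 libraries. Skin replicate 4 had a residency score of 4.796 (others 6.382 to 6.689), Cxcr6 at 339.7 TPM (1052 to 1244), Ccr7 at 1.6 TPM (9.35 to 10.23), Pdcd1 at 42.73 TPM (482.5 to 667.5), a T cell identity sum of 5650 TPM (25630 to 34670) and 41.16% of TPM in repeat loci (0.3683 to 1.839). Lymph node memory replicate 4 had a residency score of 4.401 (5.184 to 5.206), Pdcd1 at 16.66 TPM (92.57 to 107.5) and 12.07% in repeat loci (0.5869 to 2.186). Spleen replicate 4 had 23930 TPM of myeloid genes (3799 to 5156) and 6.352% in repeat loci (1.002 to 1.274). Spleen replicate 1 had Klf2 at 483.5 TPM (683 to 725.1), and spleen replicate 2 had Mki67 at 11.47 TPM (3.59 to 3.94). Naive replicate 1 had a residency score of 2.926 (2.749 to 2.767), and naive replicate 3 had Tcf7 at 665.2 TPM (628.4 to 633.3). Day 12 replicate 3 had a T cell identity sum of 33210 TPM (29020 to 29650). Lung replicate 3 had 406.2 TPM of keratinocyte genes (23.07 to 31.25) and 11430 TPM of hepatocyte genes (18.21 to 56.25). Skin replicate 3 had 652.3 TPM of hepatocyte genes (9.46 to 17.79), and tumor replicate 2 had 1017 TPM of melanocyte genes (437.8 to 476.7).

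Skin and lymph node memory cells differed in their change from spleen by a test of the difference itself. The log2 change differed by 2.26 for Cd69 (3.67 and 1.41, adjusted p = 0.00225), -2.83 for S1pr1 (-5.07 and -2.24, adjusted p = 0.0444) and 3.89 for Ifng (6.16 and 2.27, adjusted p = 6.42e-05). For the immediate early list the mean differed by 2.95 (3.82 and 0.87, adjusted p = 4.94e-51).

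Immediate early genes were higher in skin than in spleen. Digestion acting alike in every digested tissue is excluded as the sole cause, since the mean of skin exceeded that of lung, which was digested too, by 2.83 log2 (exact p = 0.0286). A different share of T cell RNA, with the same mixture of other cells, would move the markers of all other cells the same way. Skin and spleen differ in these other cells as tissues, so opposite changes cannot decide whether this share contributes. The log2 sum of B cell genes changed by -6.28 in skin (SD 1.17 in skin and 1.7 in spleen) and that of keratinocyte genes by 6.55 (SD 1.7 and 0.156; exact p = 0.0286 each). Immediate early RNA from the keratinocytes remains open, although skin replicate 4, with the most keratinocyte RNA (8560 TPM), had the lowest mean of skin (6.79), and tumor replicate 2 had a mean of 4.401 beside 2345 TPM. Digestion with collagenase IV remains possible, because liver, also digested with it, had a mean change of 2.92. Enzyme and tissue cannot be told apart. Stimulation within skin and liver may give the same values. So may other cells in liver (myeloid genes 19455 TPM), and no test separates these.

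Many genes were lower in liver than in spleen. With weights per group 46 of the 2197 stayed called. The median change of the 2197 remained -1.65 log2 while its median SE rose from 0.458 to 0.641, which ended the calls. In simulated data this fit recovered 17.9% of changes of 2 log2, against 61.2% in the main fit, so unequal spread and lost power cannot be told apart. Without liver replicate 2, the library with the fewest detected genes, 1214 genes were called in place of 2681. With T cell identity as a covariate 1554 were lower, 908 of them among the 2197, whose median change became -1.37 log2 (median SE 0.477). Without the libraries of low T cell identity 337 were lower, 191 of them among the 2197 (-0.744 log2, median SE 0.479), and 373 of the 2681 genes changed sign. A smaller share of T cell RNA stays open, since this fit keeps 1 liver library. No biological explanation was tested.

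The genes lower in skin than in spleen could come from B cells and myeloid cells in the spleen libraries. Of the 660 genes, 12.3% had means under 1 TPM in naive and day 12 libraries, against 26.8% of all tested genes. The limit of 1 TPM set for this test was wrong, because naive libraries hold 926 TPM of B cell genes. At the median spleen level of these genes, 37.3 TPM, B cells alone would bring 4.28 TPM to a naive library, so this source stays open. Removing the marker genes and rescaling left 566 genes lower, but took only 40 of the 1515 called genes out of the test, so it cannot tell. A lower level within the T cells themselves stays open too, and no test here separates it from this source.

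Splitting the 8 libraries of each comparison in all 35 ways showed how many genes other groupings call. Only the real split, 1 of 35, called as many genes in skin against spleen (1515, next 535), lymph node memory against spleen (95, next 21), skin against lymph node memory (1477, next 262), lymph node memory against day 12 (1463, next 1), tumor against day 12 (1376, next 1), day 12 against naive (2189, next 5) and spleen against naive (1201, next 23). In lung against spleen 12 of the splits called at least the 22 genes of the real one, up to 919, and in liver against spleen 3 of them called at least 2681, up to 4052. Chance is therefore not excluded for the counts of lung and liver. The split of lung replicates 1 and 4 with spleen replicates 3 and 4 called the 919 genes, which points to a structure among the samples other than the tissue.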

How the results depend on the processing

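Weights per group, quantile normalization, rescaling, the covariate and removal of libraries were chosen after results were seen. Of 236 named gene results 106 kept their side of the threshold under every alternative. Of 135 list results 35 did, with no single library left out. Unless said otherwise causes of changes were not tested. Values are genes higher, then lower. Count-based tests and scaling by size factors, scores included, were not run, as the values are not counts. Depth is unknown.

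In fits of only the 2 groups, which have fewer residual degrees of freedom and their own spread, the values were 154 and 117 (skin against spleen), 3 and 1 (lymph node memory against spleen), 0 and 0 (lung), 0 and 0 (liver), 323 higher (skin against lymph node memory), 4685 and 2234 (lymph node memory against day 12), 3924 and 4245 (tumor) and 4103 and 6639 (day 12 against naive), with 0 shared genes. Array weights gave 397 and 140 (lymph node memory against spleen), 6 lower (lung), 183 lower (liver), 1500 and 2948 (skin against lymph node memory), 6393 and 2775 (lymph node memory against day 12), 5553 and 5182 (tumor), 4334 and 7366 (day 12 against naive), 1307 and 1221 (spleen against naive) and 3 shared genes. Weights per group gave 120 and 68 (lymph node memory against spleen), 4 and 2 (lung), 138 and 46 (liver), 1784 lower (skin against lymph node memory), 5379 and 2142 (lymph node memory against day 12), 4685 and 4252 (tumor), 3951 and 7250 (day 12 against naive), 1259 and 1261 (spleen against naive) and 2 shared genes.

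Without a filter 1207 genes were lower in liver. The filter of 5 TPM, which tests fewer genes, left 497 higher (skin against spleen), 46 higher (lymph node memory against spleen), 5 lower (lung), 322 higher (skin against lymph node memory), 570 higher (tumor) and 1 shared gene. A pseudocount of 0.1 gave 7 lower (lung), 531 lower (skin against lymph node memory), 491 and 346 (lymph node memory against day 12), 587 lower (day 12 against naive), 289 lower (spleen against naive) and 2 shared genes. Quantile normalization gave 874 and 707 (liver), 973 lower (lymph node memory against day 12), 766 lower (tumor) and 848 lower (spleen against naive). The covariate gave 19 and 20 (lung) and 1118 higher (spleen against naive).

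Without the libraries of low T cell identity the values were 2183 and 1068 (skin against spleen), 2017 and 286 (lymph node memory against spleen), 650 and 244 (lung), 337 lower (liver), 1011 and 1539 (skin against lymph node memory), 1202 lower (tumor), 1467 and 2881 (spleen against naive) and 143 shared genes. In liver the T cell identity mean turned to 0.337 without these libraries and its test direction turned with the covariate (mean -0.119). Both settings use this list's own sum, so neither turn tests it. The proliferation list in liver (mean -0.0503) went down by fry and up by camera.

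The labels do not say that replicate numbers pair the samples. Libraries of the same number matched best in 9 of 36 cases, the number chance gives. Among them replicate 4 correlated at r = 0.414 (lung and spleen), 0.417 (liver and spleen) and 0.467 (skin and lymph node memory), and it held the largest share of repeat loci in 6 of the 8 groups, so a set shared by replicate 4 stays open. A replicate block with only the 2 groups gave 2 and 11 (skin against spleen), 0 and 0 (lymph node memory against spleen), 0 and 0 (lung), 0 and 0 (liver), 189 and 346 (skin against lymph node memory), 4192 and 2090 (lymph node memory against day 12), 3245 and 3896 (tumor), 3801 and 5730 (day 12 against naive), 238 and 29 (spleen against naive) and 0 shared genes.

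Leaving out each library in turn, counts ranged from 409 to 720 lower (skin against spleen), 29 to 147 higher and 11 to 31 lower (lymph node memory against spleen), 9 to 32 higher and 6 to 34 lower (lung), 370 to 786 higher and 765 to 4565 lower (liver), 417 to 710 higher and 390 to 807 lower (skin against lymph node memory), 428 to 781 higher and 388 to 483 lower (lymph node memory against day 12), 521 to 1134 higher and 248 to 489 lower (tumor), 647 to 721 lower (day 12 against naive), 246 to 736 lower (spleen against naive) and 4 to 12 shared genes. Residency score differences ranged from 2.33 to 2.96 (skin against spleen), 1.23 to 1.62 (lymph node memory against spleen), 1.35 to 1.62 (lymph node memory against day 12), 0.483 to 0.696 (tumor), 0.757 to 0.82 (day 12 against naive) and 0.576 to 0.969 (spleen against naive), where the exact test used here cannot pass with 3 libraries in a group.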

Other observations

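No hypothesis beyond those of the first part of this section was tested, and the values here were chosen after they were seen.

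The T cell receptor beta chain of nearly all libraries came from 1 variable segment. Trbv14 held 99.39 ± 0.06% of the TPM of all Trbv segments in naive cells, 99.38 ± 0.08% in the day 12 lymph node, 99.06 ± 0.14% in tumor, 98.99 ± 0.59% in skin, 98.73 ± 1.15% in lung, 97.96 ± 2.16% in lymph node memory cells, 97.6 ± 3.51% in spleen and 84.13 ± 30.1% in liver. The lowest shares were 38.99% in liver replicate 4, 92.35% in spleen replicate 4 and 94.72% in lymph node memory replicate 4.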
